A study of Mus musculus with 6 samples.

How the data were processed

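The samples were 6 two-colour Agilent whole mouse genome arrays of whole blood RNA, with FR and control RNA of the same pool number on each array and the dyes exchanged between the 2 arrays of a pool. Per the labels' protocols, RNA was extracted with a column kit and amplified and labelled with a linear amplification kit for low RNA input. The deposited scanner files hold spot intensity values on a linear scale (median signal, background median signal and processed signal for red, Cy5, and green, Cy3), extracted with Agilent Feature Extraction 11.0.1.1 per the submitters' processing notes. The series table the authors deposited holds log10 values. Set against the scanner files, each of its columns equalled the log10 ratio of red over green processed signal, with no centring added and the swapped arrays not turned. Its column medians over probe spots, for FR in Cy5 and then FR in Cy3, were -0.00938 and -0.0277 for pool 1, 0.0441 and 0.00763 for pool 2, and 0.0520 and -0.0221 for pool 3. It therefore served as an alternative after turning and centring. The direction of each ratio came from the dyes in the labels.

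Background was corrected with normexp (offset 50) on the median signal and the background median signal, where mean signals had been planned, since the scanner columns used here hold medians. Log2 ratios were normalized within arrays by loess with control spots at weight 0. Control spots and spots with outlier marks were then left out, saturated spots would have been kept, spots of a probe were averaged, and the sign was turned to FR over control. The 2 arrays of a pool were averaged. Loess sets the bulk of spots to 0 at each brightness, so the median over tested features was 0.01, and with median centring it was -0.18. Changes are relative to that centre.

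Of 41174 probes, 23374 were named by matching their accession, without version, to the RefSeq table of assembly GRCm38.p6, giving 16535 symbols. The others kept the file's identifier and were tested but are not counted among named genes. That table was used for names alone, since the array design is annotated on an older build, so no coordinates are given. A probe entered if FR or control was well above background on all 4 arrays of pools 2 and 3, and the probe with the highest mean signal stood for its gene. This left 11499 features, 7906 of them named. Several probes were kept for 1385 genes. Of the 583 changed genes among these, 86 had a probe of the opposite sign, and probes of 13 genes were called in opposite directions.

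FR against control was tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend, two-sided) on the log2 ratios of pools 2 and 3 against 0, with Benjamini-Hochberg adjustment over the 11499 features. Each ratio is taken within an array, so the pool number is a block by the construction of the array and not by shared animals. Pool 1 was kept out because its animals are those of pools 2 and 3. The slide holding pools 2 and 3 carries both diets on every array, so slide is not mixed up with diet, and pool 1 gives the values on the other slide. A gene above background in FR on none of the 4 arrays has only a bound, computed from log2 signals per channel after loess and Aquantile normalization, with the dim signals set at no less than the lowest signal among probes well above background. The ratios and list medians given here are the plain ones and not these bounds. With bounds in their place, the list medians that differed were monocyte (-0.76 against -0.78) and T cell (-0.45 against -0.46). Of the 79 genes that the naming rule took, 17 were above background in FR on 2 or 3 of the 4 arrays, including Ms4a1, Plac8, Ccl5, Hsp90b1, Foxo1, Hadhb, Fasn and Gata2 on 2. Uhrf1 and Lcn2 were not above background on all 4 control arrays.

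The test was run on simulated ratios with the real signals and 200 changed genes among 11499, in 20 runs. With the common variance of the fit, it recovered 57.5% of changes of 0.5 (log2), 99.9% of changes of 1 and 100% of larger ones, and 4.62% of calls were false. With gene variances drawn with 5.19 prior degrees of freedom, the value that 3 pools gave, it recovered 6.3%, 79.9% and 99.6% of changes of 0.5, 1 and 2, and 10.4% of calls were false. The first setting draws from the variance that the test itself assumes. In both, errors were drawn independently between genes, so deviations that genes of a pool share were not covered. The simulated changes went up or down at random, whereas 3250 features passed in the data, most of them lower. The shares recovered and false therefore need not hold for the data. A further set of genes was lowered by 0.5 (log2) for the list test and counts among the calls.

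Before the data were examined, 26 gene lists were fixed for blood cell types, other cells the blood could hold, and pathways of fasting, stress and metabolism. They were tested with limma's camera at a preset correlation of 0.01, Benjamini-Hochberg adjusted over the lists. Of 795 list members, 546 were tested. The naming rule, also fixed then, took in each direction the 15 genes with the largest log2 ratio among those past the test and of the same sign on all 6 arrays, without clone or provisional names. From each list it took the 2 members past the test with the largest ratio in each direction, or, where none passed, the 2 with the highest signal. Of the 79 genes it took, 3 are left out of the text. Other members named as examples were chosen after their values were seen. Agreement between pool 1 and the other pools and between dye orientations is described by correlations across genes and by shares of changed genes. Alternatives covered background correction, centring, dim-probe filters, replicates, dye orientation, variance model, probes per gene, thresholds and set tests.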

Results

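Whole blood of adult male C57BL/6J mice, an inbred laboratory strain, was compared between animals fed a control diet and animals given 50% food restriction (FR) for 2 weeks. The mice were 9 weeks old, with 8 animals per diet, and the blood came from the right ventricle of the heart. The series is described as a search for genes that respond to undernutrition in adult and fetal life, and the arrays analysed here ask which blood transcripts differ after restriction in the adult. RNA was pooled within each diet. Pool 1 held animals 1 to 8, pool 2 animals 1 to 4 and pool 3 animals 5 to 8. The control and FR RNA of each pool were hybridised together on 2 Agilent whole-genome arrays with the dyes exchanged, 6 arrays in all. Pools 2 and 3 share no animal and are the 2 independent replicates behind every test. Pool 1 measured the same animals again on another slide, and its values are given as a repeat measurement. Between 37.2% and 62.1% of the probe spots per array were well above background in the control channel, and between 20.4% and 55.6% in the FR channel. No spot was saturated. The number of pools limits the precision. All ratios are FR over control, and they are relative to the other transcripts of the same labelled RNA.

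Food restriction lowered many more blood transcripts than it raised. Of 7906 named genes tested, 2484 changed, with 256 higher and 2228 lower (limma, Benjamini-Hochberg adjusted p under 0.05). Ratios of at least 2-fold were reached by 544 of the lower genes and by 37 of the higher ones. The B cell receptor component Cd79b fell most, with a log2 ratio of -4.48 ± 0.27 (SD, n = 2 pools), or 22.2-fold. The other genes with the largest decreases were Fcmr, the Fc receptor for IgM, at -3.77 ± 0.31, Cd74, the MHC class II invariant chain, at -3.58 ± 0.49, the B cell surface protein Ms4a1 (CD20) at -3.48 ± 0.43, cathepsin S (Ctss) at -3.48 ± 0.88 and lysozyme 2 (Lyz2) at -3.23 ± 0.70. They were followed by Ly6d, Plac8, Ly6e, Cd52, Lyz1, the leukocyte phosphatase Ptprc (CD45), lymphotoxin beta (Ltb), the leukocyte actin-binding protein Coro1a and the platelet chemokine Ppbp, between -3.18 and -2.66. Crip2, a LIM domain protein, rose most, at 2.45 ± 0.38 or 5.48-fold. It was followed by the small GTPase Arf5 at 1.79 ± 0.55, Uhrf1, which maintains DNA methylation at replication, at 1.66 ± 0.19, Tusc1 at 1.64 ± 0.05, the mitochondrial protein Chchd10 at 1.56 ± 0.37 and the stress-responsive transcription factor Atf5 at 1.49 ± 1.15. Rpl41, the ubiquitin-conjugating enzyme Ube2j1, the amino acid transporter Slc7a5, the transcription factor E2f2, Uqcr11, Btg3, the co-chaperone Bag1, the mitochondrial folate enzyme Mthfd2 and the glutathione transferase Gstm5 lay between 1.41 and 1.22. The largest adjusted p among the 15 named higher genes was 2.06e-09 and among the 15 named lower genes 4.07e-56. With 2 pools the fit gave all genes of like signal a common variance, so these p-values overstate the certainty for single genes: with the prior degrees of freedom that 3 pools gave, 1464 genes passed, and 833 passed when the pairing of FR and control on an array was ignored (no replicate block). With pool 1 in the place of pool 2 there were 2074 changed genes, and with pool 1 in the place of pool 3 there were 4695, with animals shared between the pools in both. For 214 of the lower genes FR was not well above background on any of the 4 arrays, so the ratio does not measure the size of the fall. The number of higher genes depended on the setting, with 107 under median centring, 66 without the replicate block, 95 with the prior degrees of freedom of 3 pools, 572 with all 3 pools as replicates, 991 on the arrays with FR in Cy5 alone, 2164 with the slide as a block on 6 arrays and 1161 with pool 1 in the place of pool 3. Under each of these more genes were lower than higher.

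**Figure D1:**
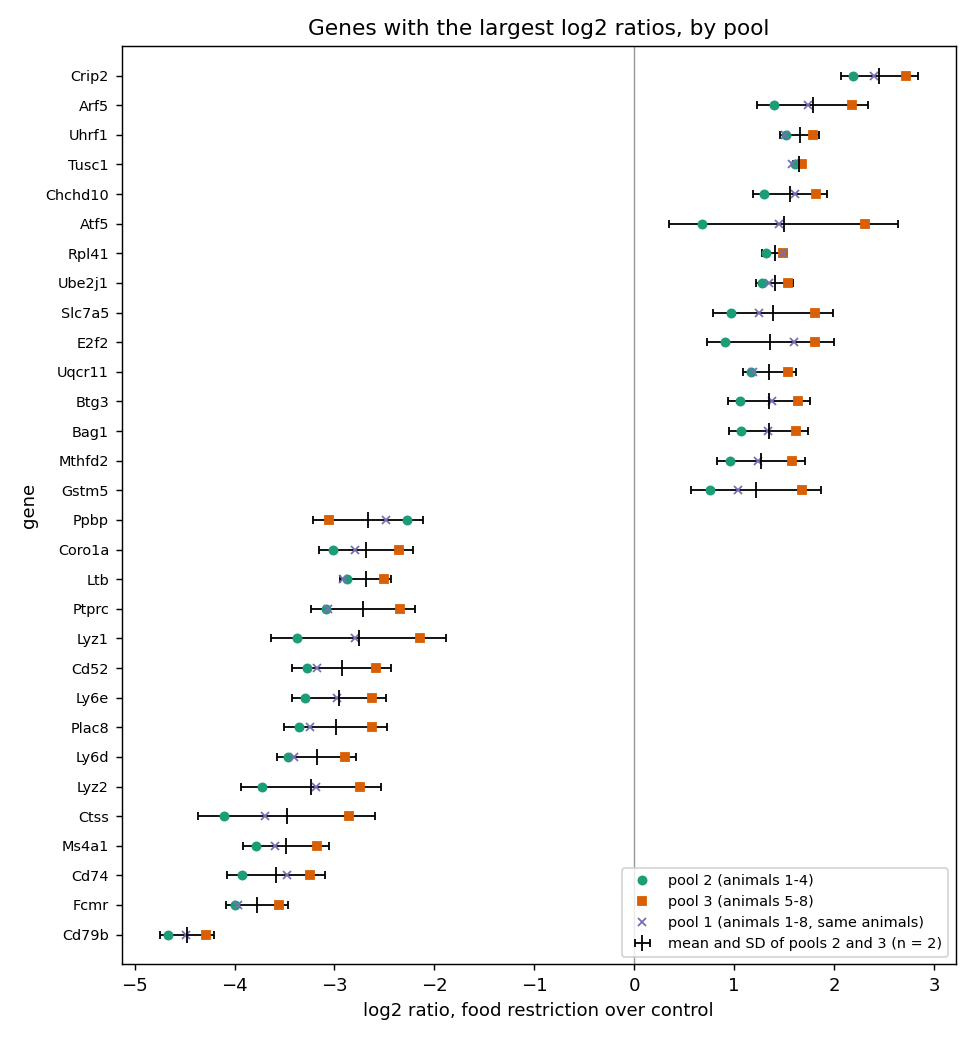
Log2 ratios (horizontal axis, FR over control) of the 15 genes with the largest increase and the 15 with the largest decrease, in pool 2, pool 3 and pool 1, with black bars for the mean and SD of pools 2 and 3 (n = 2). Cd79b lies lowest at -4.48 and Crip2 highest at 2.45, and no pool lies on the other side of 0 for any gene shown.

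Genes that mark B cells fell together. Of 21 tested members, 18 fell, none rose and 3 did not pass, with a median log2 ratio of -1.42, and 18 fell also when adjusted over the list alone. Besides Cd79b, Fcmr and Ms4a1, the coactivator Pou2af1 was at -2.47 ± 0.47 and the adaptor Blnk at -2.32 ± 0.35. Cd79a, Cr2 and Siglecg did not pass, at -0.14, -0.17 and -0.01. The list's shift relative to the other genes passed camera (adjusted p = 3.5e-09, and adjusted p = 0.866 with an estimated correlation). The ratios of dim genes are compressed by the background offset, and with Agilent's processed signals the median was -2.76. The 7 members above background in both conditions had a median of -0.62, a selection that leaves out members too dim in FR. The list for dendritic cells had 6 of 13 members lower (camera adjusted p = 0.017, and adjusted p = 0.866 with an estimated correlation, a call that also ended with processed signals or the series table, adjusted p = 0.203, and with both conditions above background, 0.137), and Cd74, H2-Aa at -2.54 ± 0.82 and H2-Ab1 at -2.53 ± 0.42 led it together with Ly6d at -3.18 ± 0.40, genes that B cells express too. Of 3 tested plasma cell and immunoglobulin genes, the endoplasmic reticulum protein Creld2 fell to -0.43 ± 0.01 (a call that ended with processed signals, adjusted p = 0.0783), and the list did not pass camera (adjusted p = 0.551).

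Monocyte and macrophage markers were lower in 17 of 20 members, with a median of -0.78, or -1.14 in pool 2 and -0.44 in pool 3 (camera adjusted p = 1.34e-06, and adjusted p = 0.866 with an estimated correlation). Ctss and Lyz2 led, and the coagulation factor XIII subunit F13a1 at -1.45 ± 0.05 and the receptor Csf1r at -1.10 ± 0.56 were among the others, while Chil3, Ace and Cd14 did not pass. Among T cell markers 10 of 20 fell (median -0.46, camera adjusted p = 0.0137, and adjusted p = 0.866 with an estimated correlation and 0.569 with both conditions above background), with Cd3d at -1.89 ± 0.25, Thy1 at -1.88 ± 0.33 and the kinase Lck at -1.39 ± 0.33, whereas Cd3e and Cd3g were at -0.05 and -0.12. Of 8 NK and cytotoxic cell markers 5 fell (median -0.61, camera adjusted p = 0.00171, and adjusted p = 0.866 with an estimated correlation), among them the chemokine Ccl5 at -1.67 ± 0.30 and the granule protein Nkg7 at -1.52 ± 0.30. Neutrophil markers were mixed. The lectin Clec4d at -1.51 ± 0.03 was among 8 of 25 members that fell, Lcn2 was the 1 member that rose, at 0.32 ± 0.40 (a call that ended with median centring, without background subtraction and with all 3 pools as replicates), and the list did not pass camera (adjusted p = 0.0939, but 0.0454 with both conditions above background and 0.0393 with pool 1 in the place of pool 3). Among 7 eosinophil and basophil markers, Gata2 fell to -0.33 ± 0.07, a call that ended when adjusted over the list alone, and the list did not pass camera (adjusted p = 0.593). Its median of 0.11 and mean of -0.01 differed in sign.

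Platelet and megakaryocyte markers were lower in 17 of 24 members, with a median of -0.90 (camera adjusted p = 4.48e-07, and adjusted p = 0.866 with an estimated correlation). Ppbp was at -2.66 ± 0.55, the ADP receptor P2ry12 at -2.07 ± 0.32, the regulator of G protein signalling Rgs18 at -1.82 ± 0.32 and the platelet glycoprotein Gp9 at -1.17 ± 0.05. Every member that fell was above background in FR on all 4 arrays. Pf4 (platelet factor 4) was at -0.88 ± 0.00, and 7 members including Itgb3 and Selp did not pass.

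Erythroid and reticulocyte genes went both ways. Of 40 tested members 6 rose, 5 fell and 29 did not pass, with a median of 0.08 (-0.13 in pool 2 and 0.21 in pool 3). Camera gave an adjusted p of 0.0834, but toward higher values 0.0422 without background subtraction, 0.0219 with median centring, 0.0233 without a dim filter and 0.000403 with pool 1 in the place of pool 2. The mitochondrial iron importer Slc25a37 was at 1.05 ± 0.61 and the transferrin receptor Tfrc at 0.68 ± 0.41, while the transcription factor Nfe2 was at -1.19 ± 0.16. The globin gene Hba-a1 and the heme synthesis enzyme Alas2, at 0.02 ± 0.22 and 0.09 ± 0.27, did not pass. Cell cycle genes were split as well, with 5 of 25 higher and 7 lower (camera adjusted p = 0.531, median 0.08 and mean -0.02). Uhrf1 at 1.66 ± 0.19 and the mitotic cyclin Ccnb2 at 1.03 ± 0.05 rose, and the spindle protein Nusap1 at -1.95 ± 0.19 and the replication clamp Pcna at -0.70 ± 0.28 fell.

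Genes of the type I interferon response fell in 16 of 20 members (median -0.68, camera adjusted p = 2.59e-06, and adjusted p = 0.866 with an estimated correlation), led by Ifi27l2a at -2.51 ± 0.16, the ubiquitin-like protein Isg15 at -2.12 ± 0.29 and the transcription factor Irf7 at -1.63 ± 0.26. Heat shock and chaperone genes fell in 11 of 22 (median -0.33, camera adjusted p = 0.000414, and adjusted p = 0.866 with an estimated correlation), with the constitutive chaperone Hspa8 at -2.25 ± 0.21 and the endoplasmic reticulum chaperone Hsp90b1 at -1.65 ± 0.59. Glycolysis and hypoxia genes fell in 13 of 21 (median -0.49, camera adjusted p = 0.0012, and adjusted p = 0.866 with an estimated correlation), among them lactate dehydrogenase Ldha at -1.63 ± 0.23 and triose phosphate isomerase Tpi1 at -1.63 ± 0.07. These members are also transcribed in white cells, whose markers fell in the same pools.

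Lists that relate to fasting were read in the same blood, with the white cell and platelet markers lower. Fatty acid oxidation and PPAR target genes fell in 7 of 14 (median -0.30, or -0.43 in pool 2 and -0.15 in pool 3, camera adjusted p = 0.0347, and adjusted p = 0.866 with an estimated correlation), with the beta-oxidation enzymes Hadhb at -1.10 ± 0.23 and Acaa2 at -0.85 ± 0.53. The list's call ended when either pool was replaced by pool 1 (adjusted p = 0.15 without pool 2 and 0.0615 without pool 3), and also with scale normalization, both conditions above background, no replicate block and the variance models without trend or robust (0.0668 to 0.338). The glucocorticoid-responsive list had 6 of 14 members lower and none higher (camera adjusted p = 0.182). Rgs2 at -1.44 ± 0.64 and Txnip at -1.16 ± 0.74 fell most, and Fkbp5 did not pass, at 0.19. Among 20 amino acid response (ATF4) genes 4 rose (the list passed toward higher values relative to other genes with median centring, adjusted p = 0.0454), namely Slc7a5 at 1.39 ± 0.60, Mthfd2 at 1.27 ± 0.44, Nars at 0.70 ± 0.54 and Asns at 0.41 ± 0.15, and the translation inhibitor Eif4ebp1 fell to -1.63 ± 0.08 (camera adjusted p = 0.197). Autophagy and FoxO target genes had 3 of 23 members higher and 11 lower (camera adjusted p = 0.237, and 0.0296 toward lower values without a dim filter). The mitophagy kinase Pink1 was at 0.72 ± 0.56, a call that ended with the prior degrees of freedom of 3 pools (limma adjusted p = 0.0663) and without the replicate block (0.0849). The mitochondrial superoxide dismutase Sod2 was at 0.62 ± 0.28, a call that ended with median centring (adjusted p = 0.117) and without the replicate block (0.0656). The transcription factor Foxo1 was at -1.59 ± 0.37 and Atg12 at -1.37 ± 0.07. Sterol and fatty acid synthesis genes fell in 4 of 13 (camera adjusted p = 0.534), with Fasn (fatty acid synthase) at -1.08 ± 0.39. Immediate early genes fell in 8 of 16 (camera adjusted p = 0.0939, but 0.0440 with median centring, 0.0275 without a dim filter, 0.0234 without trend, 0.0306 with the robust model and 0.0167 with pool 1 in the place of pool 3), with Ier5 at -2.04 ± 0.44 and Klf6 at -1.36 ± 0.23. Of 6 circadian clock genes, only the kinase gene Csnk1e passed, at -0.59 ± 0.03 (camera adjusted p = 0.816, median 0.01 and mean -0.11).

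Cytosolic ribosomal protein genes split, with 12 of 77 higher and 31 lower (median -0.23, or -0.40 in pool 2 and -0.06 in pool 3, camera adjusted p = 0.266, but toward lower values 0.0120 without a dim filter, 0.0352 with both conditions above background and 0.00682 with pool 1 in the place of pool 3). Rpl41 at 1.41 ± 0.12 and Rplp1 at 1.03 ± 0.33 rose, and Rps18 at -2.11 ± 0.82 and Rps27 at -1.93 ± 0.31 fell. Oxidative phosphorylation genes split in the same manner, with 16 of 71 higher and 29 lower (median -0.18, or -0.36 in pool 2 and -0.04 in pool 3, camera adjusted p = 0.463, and 0.0232 toward lower values without a dim filter; with pool 1 in the place of pool 2 the direction was higher, at 0.876). The complex III subunit Uqcr11 was at 1.35 ± 0.27 and the cytochrome oxidase subunit Cox4i1 at 1.19 ± 0.36, against the cytochrome oxidase subunit Cox5a at -2.40 ± 0.17 and the ATP synthase subunit Atp5g3 at -1.73 ± 0.25. For cells that blood drawn from the heart could also hold, none of 7 cardiac muscle markers passed (camera adjusted p = 0.0834, and 0.0289 toward higher values without a dim filter, Mybpc3 at 0.10 ± 0.06 and Cox7a1 at 0.21 ± 0.11). Cox7a1 passed with all 3 pools as replicates (adjusted p = 0.0421) and with the slide as a block on 6 arrays (0.000893), and Mybpc3 with the latter (0.0339). None of 6 hepatocyte markers passed either (camera adjusted p = 0.531, Tat at 0.04 ± 0.02 and Ahsg at 0.06 ± 0.25). At an unadjusted p under 0.05, limma passed 1 of the cardiac members and 0 of the hepatocyte ones. Of 10 endothelial markers, Ly6c1 at -0.94 ± 0.77, also a monocyte gene, and Esam at -0.52 ± 0.09 (a call that ended with processed signals, adjusted p = 0.0536) fell (camera adjusted p = 0.959).

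In total 10 of the 26 lists passed camera with its preset correlation between genes, all toward lower values. With a correlation estimated from the 2 pools none passed (smallest adjusted p = 0.866 with an estimated correlation), and the self-contained test fry passed none (smallest adjusted p = 0.105). Both rest on the spread between only 2 pools, which leaves them little power, so their failure to pass decides little. The 10 calls in turn rest on the preset correlation of 0.01. The estimates for these lists, themselves from 2 pools, were 1 for NK, 0.81 for B cell and 0.80 for monocyte markers. They were 0.47 for fatty acid oxidation, 0.33 for interferon, 0.24 for glycolysis and 0.09 for heat shock genes. For dendritic, T cell and platelet markers they were 0.08, 0.04 and -0.04. Where members vary together between pools, the preset value makes the camera p-values too small. At an unadjusted p under 0.05, camera with an estimated correlation passed 0 lists and fry passed 2. Adjusted over the list alone, the counts of members that rose or fell were those over all genes for most lists. They differed for autophagy (3 higher, 12 lower), ribosomal proteins (14 and 33), oxidative phosphorylation (17 and 32), dendritic cells (1 and 7), neutrophils (1 and 9), heat shock (0 and 13), NK cells (0 and 8) and eosinophils (0 and 0). With median centring the medians of the erythroid, cell cycle, ATF4, circadian, eosinophil, hepatocyte and cardiac lists turned from above to below 0, and with processed signals the erythroid, circadian and endothelial medians changed sign. Processed signals also made the median lower for NK (-1.99), monocyte (-1.84), interferon (-1.62), heat shock (-1.21), T cell (-1.13), glycolysis (-0.91), fatty acid oxidation (-0.83), dendritic (-0.78), autophagy (-0.55), immediate early (-0.54), sterol (-0.45), oxidative phosphorylation (-0.36), ribosomal protein (-0.35) and plasma cell (-0.29) lists. Median centring made the median of every list lower. It moved the oxidative phosphorylation median to -0.41 and the ribosomal one to -0.36. Among the others, it gave -0.56 for heat shock, -0.56 for dendritic, -0.53 for immediate early, -0.53 for autophagy and -0.52 for fatty acid oxidation genes. It gave -0.42 for neutrophil, -0.42 for glucocorticoid-responsive, -0.39 for plasma cell, -0.26 for endothelial and -0.20 for sterol genes. The eosinophil and circadian medians were above 0 in pool 2 (0.18 and 0.03) and below 0 in pool 3 (-0.04 and -0.08). The circadian median also changed sign with scale normalization and the endothelial median with the offset of 16.

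**Figure D2:**
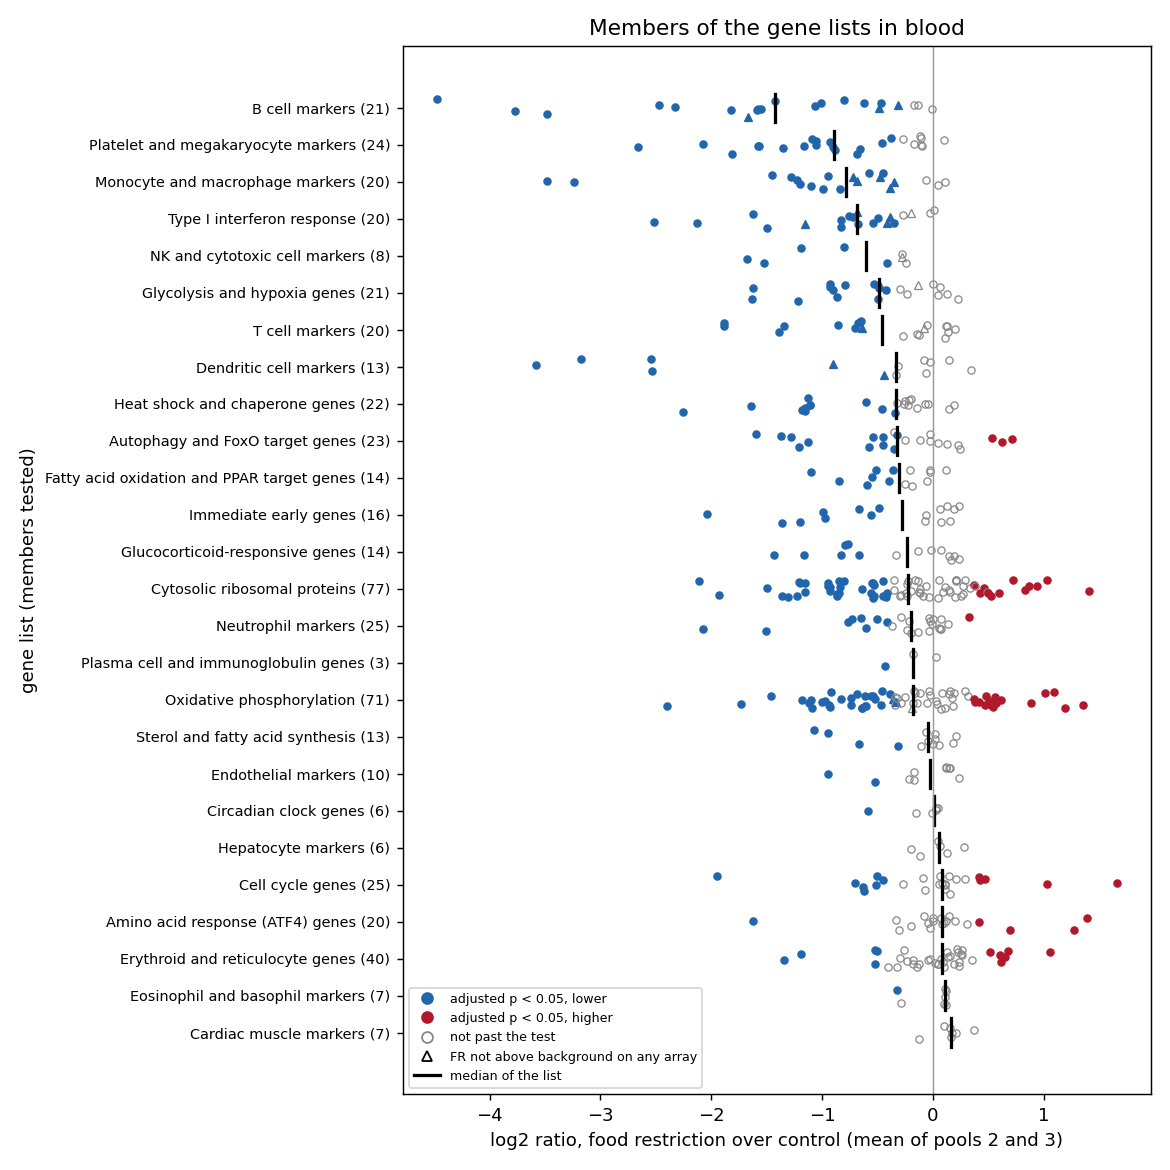
Log2 ratio of each tested member (horizontal axis, FR over control, mean of pools 2 and 3) for the 26 gene lists, with filled points past the test, open points not past it, triangles where FR was not above background on any array and black bars for the list medians. B cell markers have the lowest median, at -1.42, and the ribosomal protein and oxidative phosphorylation lists spread to both sides of 0.

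The repeat measurement in pool 1 ran close to the other pools. Across genes, which are not independent replicates, its log2 ratios correlated with the mean of pools 2 and 3 at r = 0.968. Of the 2484 changed genes, 2483 had the same sign in pool 1 and 2439, or 98.2%, had at least 50% of the log2 ratio there. Pools 2 and 3 correlated at r = 0.853 across genes. The lower genes averaged -0.96 in pool 2, -0.64 in pool 3 and -0.90 in pool 1, and the higher genes averaged 0.46, 0.82 and 0.58. Lyz2, for example, was at -3.73 in pool 2 and -2.74 in pool 3, and Atf5 at 0.68 and 2.31.

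The dye orientations mostly gave the same direction after loess. With the sign turned to FR over control, the 2 arrays of a pool correlated across genes at r = 0.838 in pool 1, 0.875 in pool 2 and 0.787 in pool 3. Of the changed genes, 2385 (96.0%) had 1 sign on all 4 arrays of pools 2 and 3, and 2362 (95.1%) on all 6 arrays. With median centring in place of loess the mean correlation fell from 0.833 to 0.401, and 63.9% of the changed genes had 1 sign on all 6 arrays.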

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

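Tests chosen after the data were seen are the fits with other prior degrees of freedom, with 6 arrays and with pool 1 in the place of a pool. No gene named by rule that passed, and no list that passed, turned to the opposite direction under any alternative run for it. The total of 2484 changed genes stayed within 1.5 times under other background corrections, scalings, probe rules, single dye orientations, variance models (without trend, robust), 4 arrays with pool as a block, a threshold of 0.1 and the series table, from 2302 to 3553. With median centring 107 genes were higher and 3211 lower. There the centre moves to -0.18 and the loess correction by brightness is left out. For the higher genes the 2 were not told apart. With median centring and the centre set back to 0, 2013 of the 2228 lower genes stayed lower and past the test. Requiring both conditions above background gave 1317 genes, 1052 of them lower, because genes too dim in FR no longer enter. Using all 3 pools as replicates, which repeats animals, gave 572 higher genes. The arrays with FR in Cy5 alone gave 991 higher genes, and the cause was not tested. With the pairing on an array ignored (no replicate block), 833 genes passed, 66 higher and 767 lower, all among the 2484; of 10 lists past camera, 9 passed. The prior degrees of freedom of 3 pools gave 1464 (95 and 1369), all among the 2484. The slide as a random block on 6 arrays gave 5569 (2164 and 3405). For 3 pool values duplicateCorrelation gave no correlation, so that planned fit was not run. Ratios of at least 1.5-fold on all 4 arrays were found for 738 genes (43 and 695) and on all 6 arrays for 711 (40 and 671). With pool 1 in the place of pool 2 or pool 3 the totals were 2074 and 4695, with 297 and 1161 higher and 1777 and 3534 lower. A single pool has no spread to test and gave values alone.

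For the gene lists, 10 passed camera, and 16 without a filter on dim probes. With an estimated correlation 0 passed and with fry 0 passed, against 0 and 2 at an unadjusted p under 0.05. Both tests take their spread from only 2 pools and have little power. Their failure to pass therefore decides little about the 10 lists, whose calls rest on the preset correlation. The other list alternatives gave 8 to 13. The fatty acid oxidation list lost its call under 9 alternatives, with adjusted p of 0.338 when both conditions had to be above background and from 0.00119 to 0.866 over its alternatives. Erythroid genes passed, toward higher values relative to other genes, with median centring (adjusted p = 0.0219), without background subtraction (0.0422), without a dim filter (0.0233) and with pool 1 in the place of pool 2 (0.000403), against up to 0.930 over its alternatives.

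Among genes named by rule, calls of Lcn2, Gata2, Esam, Creld2, Sod2, Tfrc, Pink1, Txnip, Ly6c1, Acaa2, Pcna and Csnk1e were lost under 1 or more alternatives, 12 of them without the block and 7 with the prior degrees of freedom of 3 pools. Agreement of pool 1 with the other pools was r = 0.929 without a dim filter. The share of changed genes with at least 50% of the ratio in pool 1 was 90.5% with processed signals, 98.7% without background subtraction, 90.8% with median centring, 96.5% without a dim filter and 96.7% with both conditions above background. The mean correlation between dye orientations, 0.833, was 0.765 with processed signals, 0.401 with median centring and 0.643 without a dim filter. The share of changed genes with 1 sign on all 6 arrays was 93.7%, 63.9% and 90.5% under these settings. Signal over background limits the lower genes: 1031 of the 2228 had FR above background on all 4 arrays.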

Other observations

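All gene families below were chosen after the values were seen, as were the tests of dilution, dye bias, loess centring and brightness. Named genes were grouped by the letters before the first digit or hyphen of the symbol, except that symbols beginning with H2- formed a family of their own, and the 108 families with at least 8 tested members were tested with camera. Of these, 10 passed with the preset correlation and 0 with an estimated correlation (adjusted p = 0.957 for each, and 0 at an unadjusted p under 0.05). The latter test has little power with 2 pools, so the calls rest on the preset correlation. Genes with symbols that begin with H2-, of the MHC region, fell in 13 of 18 members (median -1.03, adjusted p = 7.3e-06), with the class I gene H2-Q7 at -1.83 ± 0.58 (SD, n = 2) and H2-T23 at -1.54 ± 0.63. Genes with symbols that begin with Irf fell in 7 of 8, and the member that did not pass is no interferon regulatory factor but a protein that binds 1 (median -1.12, adjusted p = 0.00369), with Irf8 at -2.01 ± 0.38 and Irf1 at -1.66 ± 0.63. Proteasome beta subunits fell in 8 of 9 (median -0.89, adjusted p = 0.00053), with the immunoproteasome subunits Psmb10, Psmb8 and Psmb9 at -1.67, -1.54 and -1.30. Mitochondrial ribosomal proteins of the large subunit fell in 22 of 38 and rose in 2 (median -0.42, adjusted p = 0.000776). Some of those that fell, such as Mrpl36 and Mrpl41, were above background in FR on 0 arrays of the fit, so their ratios do not measure the size of the fall. Mitochondrial ribosomal proteins of the small subunit fell in 7 of 22, and that family did not pass (median -0.23, camera adjusted p = 0.193). Genes with symbols that begin with Eif, which are translation initiation factors and some of their inhibitors and other partners, fell in 17 of 43 and rose in 2 (median -0.30, adjusted p = 0.0211), with Eif3c at 0.83 ± 0.50 among the latter.

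Olfactory receptor genes gave 282 features above background, 0 of them higher and 6 lower by limma (8 higher at an unadjusted p under 0.05), with a median of 0.12 that became -0.08 with median centring. Their family passed camera toward higher values (adjusted p = 4.92e-06), and so did collagen genes (Col), with 0 of 21 higher (3 at an unadjusted p under 0.05) and a median of 0.16 that became -0.03, and synaptotagmins (Syt), with 2 of 9 higher and a median of 0.19 that became 0.04. With an estimated correlation these 3 families did not pass (adjusted p = 0.957). Whether these probes measured their own transcripts was not tested.

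Marker genes of white cells and platelets were lower, 75 of them over the 6 lists for B, T, NK, monocyte, neutrophil and platelet genes. Dye bias is argued against by the median over all 118 tested members of these lists, which lay below 0 on each array in both dye orientations. The highest was -0.36, with a 95% interval of -0.56 to -0.20. That interval is over genes of 1 array taken as independent, and it does not measure the spread between pools. Loess centring is argued against by 94.7% (71 of 75) of those that fell staying lower and past the test with median centring and the median of all tested features set to 0, where 2013 of all 2228 lower genes stayed. The 75 were picked as lower under loess on the same arrays, so the check covers these members alone. Among the 63 members above background in both conditions, whether they fell or not, list medians ran from -1.52 for NK cells to -0.05 for T cells, a range of 1.47 with a permutation p = 0.155 from permuting members over lists. This decides little, since only 1 NK marker and 7 of 21 B cell markers were bright enough in FR to enter and the fall itself removes the others. From pool 2 to pool 3, medians of all tested members went from -1.63 to -1.21 for B cells, -1.14 to -0.44 for monocytes and -0.55 to -0.33 for T cells. They went from -0.73 to -0.48 for NK cells, -0.42 to -0.08 for neutrophils and -0.85 to -0.88 for platelets. Platelet markers thus did not move with white cell markers, which goes against 1 dilution shared by both. That difference was not tested, and each median rests on 1 pool. Among white cells, 1 common dilution cannot be told apart from cell-specific changes. Fewer circulating white cells and platelets per red cell may explain the pattern, as may lower transcript levels within the cells, and no cell counts were analysed here.

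Ribosomal protein and oxidative phosphorylation genes moved both ways. Error of single probes is argued against by 36 genes with 82 probes, in which the SD between probes of a gene was 0.252 of the SD between all these probes (permutation p = 1e-05, the smallest that the permutations can give). Cross-hybridisation or pseudogene copies shared by the probes of a gene would leave them in agreement too, so these effects are not decided. Genes with 1 probe stay open. Without loess, the slope of the log2 ratio on mean signal was 0.10 ± 0.02 (SE) in these lists. Among 7500 other genes in the same signal range it was -0.01, a quotient of -0.0769. This argues against a linear bias with brightness shared by all genes over that range. The other genes were not matched to the lists in brightness within it, so a bias among bright genes alone is not decided. After loess, the rank correlation of ratio and mean signal was 0.32 in the lists and 0.01 among the others. A change in the mix of white cells and reticulocytes may lie behind the split and was not tested.

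Pools 2 and 3 differed in size of change. Of 57 features more than 1 (log2) apart between these pools on the arrays with FR in Cy5, 98.2% differed in the same direction with FR in Cy3, which argues against error of single arrays. Changed genes were shifted upward in pool 3 against pool 2, by a median of 0.33 for those higher and 0.31 for those lower, and genes that did not change, which loess holds near 0, by -0.04. Pool 1, made from all the animals, lay between the 2 pools, at -0.90 against -0.96 and -0.64 for lower genes and 0.58 against 0.46 and 0.82 for higher ones, and correlated at r = 0.951 with pool 2 and 0.910 with pool 3. Different animals in the pools may account for the difference, as may the pooling or labelling of each RNA, and these values do not decide between them.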
